A study of Homo sapiens with 6 samples.

How the data were processed

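RNA of sorted CD24+ and CD24− cells from ARP1, OCI-MY5 and OPM2 was measured on Affymetrix Human Genome U133 Plus 2.0 arrays. Per the labels' protocols, the lines were grown in RPMI-1640 with serum, sorted by flow cytometry with a CD24 antibody, and their total RNA was extracted with a silica column kit. Biotinylated cDNA was made from 100 ng of total RNA, and each sample was hybridised to 1 array. Per the submitters' processing notes and the series' design text, the authors computed values with the MAS5 algorithm of Affymetrix Expression Console 1.1. MAS5 estimates a background and a mismatch signal for each probe pair, takes a robust mean over the pairs of a probe set, and scales each array by 1 factor. The deposited values are MAS5 intensity on a linear scale, 1 per probe set and array. In the deposited table the mean without the lowest and highest 2% of values was 499.9 on every array, and nothing beyond that scaling was applied between arrays as far as the values show. Raw scanner files, detection calls and scan dates were not used here.

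Of 54675 probe sets, 62 control probe sets were left out of the gene tests. Gene names came from the platform's annotation table, matched by Entrez ID to the RefSeq gene table of GRCh38.p14 for current symbols, and 41043 probe sets matched. There were 41091 probe sets with 1 gene symbol, 1801 with several and 11721 with none, and only the first kind was named. These stood for 19775 genes. Each gene was represented by its probe set with the highest mean over the 6 arrays, and 12078 genes with a mean log2 value of at least 6.36, the median of all probe sets, were tested. Values were transformed as log2(intensity + 16). Probe sets whose names end in x_at can bind transcripts of related genes; 9 of the 36 ribosomal protein genes are represented by one.

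Samples were grouped by the CD24 label in their titles, 3 per group. The numbers in the titles, 1 to 3, stand for the cell lines, so samples with the same number come from the same line. Deviations from the group means correlated at 0.70, 0.71 and 0.77 between the fractions of ARP1, OCI-MY5 and OPM2, and at −0.58 to 0.15 between fractions of different lines, so the numbers pair the samples. The series' design text states a comparison of CD24+ with CD24− and no pairing. The main test therefore had no block, and the cell line as a block was the alternative fit. No label says that the arrays of a group came from repeated cultures of a line. The p-values of the gene tests between the fractions measure the spread between these 3 lines with 1 array each, biological and technical together. Tests between lines take the CD24+ and CD24− arrays of a line as its replicates.

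Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over lists, with an estimated correlation and with fry, which tests a list against no change, as alternatives. Camera sets a list against the other genes, so with the preset correlation its p-values do not measure the spread between lines. The 33 lists cover stem cell, drug efflux, developmental pathway, B cell and plasma cell, cell cycle, stress, metabolic, DNA repair, survival, inflammatory and ribosomal genes, and markers of other cell types; 30 had at least 5 tested genes. They hold 830 genes, of which 753 were named by a probe set of their own and 607 were tested. Single measures per array were compared within lines with an exact sign-flip test, chosen after the values were seen because the arrays pair by line; the exact permutation test over arrays fixed beforehand gave p = 0.7 for the ACTB ratio, 0.2 for the spike-ins and 0.2 for the median intensity, where 0.1 is the lowest possible. Shares of variance are sums of squares of line, fraction and remainder per gene. Because each line has 1 array per fraction, a difference within a line has no replicate check.

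The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. The rule named CD24, and of the genes past the adjusted threshold the 10 with the highest and the 10 with the lowest mean difference. Where fewer passed, places went to genes with the same direction in all 3 lines, ranked by the smallest of their 3 differences; all 20 places were filled this way. From each list it took members past the threshold and up to 4 members with the largest mean difference among those with the same sign in all lines. Some list genes are not reported here.

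Alternatives were pseudocounts of 1 and 64, other filters on dim genes, quantile normalization, median centring, the mean of all probe sets of a gene, every probe set on its own, an intensity trend in the prior variance, the block, other fold limits, and leaving out each line and each array. Fits without 1 array had no block, so the line left with 1 fraction adds a difference between lines to that between fractions. The gene tests were checked on data simulated from the real means and spreads with 200 changed genes in each of 5 runs. Of unchanged genes the unblocked test called 0% and the blocked test 0.0202%. In 20 simulated runs camera made 1 false call over the 30 lists of each run and called a list shifted by 0.5 in all 20. The simulated genes were drawn independently of each other, so this check says nothing about correlation between genes. Figures were drawn with matplotlib 3.10.9.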

Results

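Gene expression was measured in CD24+ and CD24− cells of ARP1, OCI-MY5 and OPM2, 3 human lines grown from multiple myeloma, a cancer of antibody-secreting plasma cells. CD24 is a small glycosylated protein of the cell surface, and the cells were sorted by flow cytometry with an antibody against it. Each line gave 1 array of its CD24+ and 1 array of its CD24− fraction, so each group held 3 arrays. The study set the CD24+ fractions, which its submitters describe as cancer stem cell populations, against the CD24− fractions. Values were deposited MAS5 intensities of 54675 probe sets, and 12078 genes were bright enough to be tested. The number of arrays, 3 per group and 1 per line and fraction, limits the precision of every comparison. Differences are CD24+ minus CD24− on the log2(intensity + 16) scale, which understates the change of dim genes.

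The CD24+ array of OPM2 stood apart from the other 5 arrays in its spike-in controls and its median intensity. Its bacterial spike-in transcripts, which the usual protocol adds before hybridisation, had a geometric mean intensity of 45533, against 7395.5 to 8972 on the others. That is 5.36 times the median of the others. Its median intensity over all probe sets was 135, against 69.0 to 84.2. GAPDH and ACTB each have probe sets at the 3′ and 5′ ends of the transcript, whose signal ratio grows as RNA or its copies become shorter. The ACTB ratio was 2.63 and 2.47 in the CD24+ and CD24− cells of ARP1, 9.36 and 23.2 in those of OCI-MY5, and 27.1 and 7.54 in those of OPM2. The GAPDH ratio was 1.27 and 1.27, 2.34 and 5.16, and 5.98 and 1.52 in the same order. Mean log2 ACTB ratios of the groups were 3.13 ± 1.68 and 2.92 ± 1.61 (SD, n = 3; exact sign-flip p over the 3 lines = 0.75, two-sided). Within each line the CD24+ array had the higher spike-ins and the higher median intensity. The log2 differences were 0.20 in ARP1, 0.12 in OCI-MY5 and 2.38 in OPM2 for the spike-ins and 0.14, 0.12 and 0.90 for the median (exact sign-flip p = 0.25 for each, the lowest that 3 pairs can give).

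**Figure D1:**
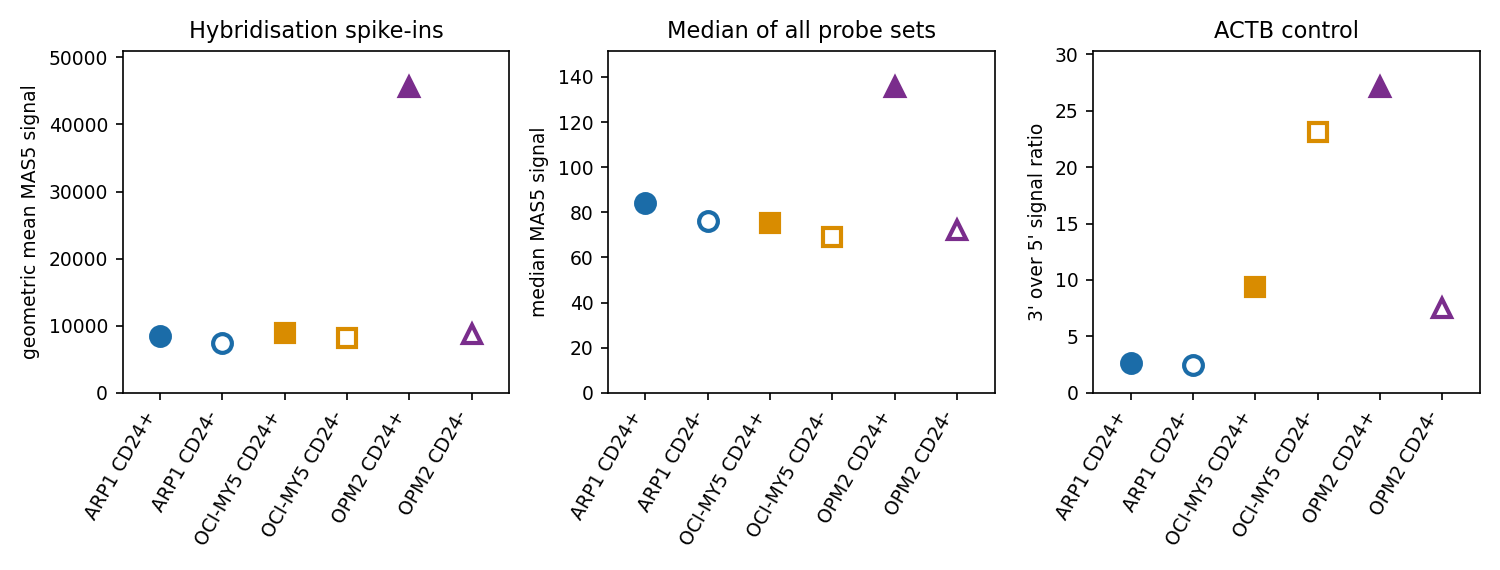
Spike-in intensity (geometric mean of 9 probe sets), median intensity of all probe sets and ACTB 3′ over 5′ signal ratio of each of the 6 arrays, on linear axes; circles are ARP1, squares OCI-MY5 and triangles OPM2, filled for CD24+ and open for CD24−. The OPM2 CD24+ array has a spike-in intensity of 45533 and a median of 135, above the other 5 arrays in both.

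CD24 itself was near background on these arrays and gave no check of the sort. Its 6 probe sets had intensities from 1.69 to 140, with a median of 29.8, and all 6 lay below the brightness limit for testing. Control probe sets for TrpnX, a bacterial transcript that is not among the spike-ins, ran from 2.23 to 96.4 with a median of 9.92. On the brightest CD24 probe set the CD24+ arrays were higher by 0.77 ± 1.33 (log2, SD over 3 lines). The difference was −0.49 in ARP1, 2.16 in OCI-MY5 and 0.63 in OPM2 (limma, adjusted p = 0.809 over the 6 probe sets). Over all 6 probe sets mean differences ran from −0.69 to 0.77, and none had the same direction in all 3 lines.

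Cell line accounted for most of the variation in transcript levels, and CD24 fraction for little. For the median gene, line took 77.5% of the sum of squares, fraction 4.76% and the remainder 11.7%. The share of the fraction was 11.3% with each array centred on its median, and 10.2% to 11.3% without a line, which leaves fewer arrays per gene; that of the line stayed above 61% in every setting run. The CD24+ and CD24− arrays of a line correlated at r = 0.975 in ARP1, 0.976 in OCI-MY5 and 0.936 in OPM2, across genes, which are not independent replicates. At least 2-fold apart were 5.07% of genes in ARP1, 5.72% in OCI-MY5 and 18.2% in OPM2, where on the deposited scaling 1571 were higher and 629 lower in CD24+ cells. The measured differences shared little between lines. Across genes Pearson's r was 0.039 for ARP1 with OCI-MY5, 0.030 for ARP1 with OPM2 and 0.034 for OCI-MY5 with OPM2, and Spearman's rho was 0.039, 0.052 and 0.074. Noise may hold these values down. Within a line, 2 probe sets of the same gene correlated at only 0.076 in ARP1, 0.166 in OCI-MY5 and 0.148 in OPM2. With 1 array per line and fraction, noise and real differences between lines cannot be told apart.

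Most genes with the steadiest differences between the fractions were dim: of the 20 named by a rule that ranks genes by the smallest of their 3 differences, 16 lay in the lowest 25% of tested genes by mean intensity. ZMIZ1-AS1, an antisense transcript, was higher in CD24+ cells by 1.85 ± 0.18 (log2, mean ± SD, n = 3 lines), and BEGAIN by 1.58 ± 0.25. The intergenic RNA LINC02487 was higher by 1.80 ± 0.30, and ALG12, a mannosyltransferase of N-glycan assembly, by 1.52 ± 0.39. MFAP2, a protein of extracellular microfibrils, was lower by a log2 difference of −1.66 ± 0.46. F2R, the thrombin receptor, differed by −1.21 ± 0.61, BCL11A, a transcription factor of B lymphoid cells, by −1.17 ± 0.69, and MCAM, the adhesion molecule CD146, by −0.98 ± 0.39. PTP4A1, a protein tyrosine phosphatase and the brightest of those named, differed by −0.85 ± 0.37, from 3239 to 1327 intensity units in ARP1. These values rest on the brightest probe set of each gene. With the mean of all its probe sets PTP4A1 differed by −0.01, BCL11A by −0.26, GK5 by −0.25, F2R by −0.61 and MCAM by −0.66. Of the other 15 named genes 9 have 1 probe set, and 6 fell below the brightness limit as a mean. Of the 20, BCL11A, F2R, IRF2BP1, LINC02487, LINC02604, MCAM, RAB4B and ZSWIM5 had both arrays of 1 line within the range of the TrpnX controls. CLCA4-AS1 and ZNF493 had this in more than 1 line. Differences in those lines are uncertain.

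None of these genes, nor any other of the 12078, passed limma's test at a Benjamini-Hochberg adjusted p of 0.05. Without adjustment 149 genes had p below 0.05, of which 136 were higher and 13 lower in CD24+ cells, or 66 and 36 with quantile normalization and 44 and 40 with centring. With the cell line as a block 0 genes passed as well, with 560 below 0.05 unadjusted (466 higher and 94 lower, or 304 and 186 with quantile normalization and 171 and 460 with centring) and a lowest adjusted p of 0.847. With no change in any gene and independent arrays 604 would be expected, and the variation between lines, which the unblocked test counts as noise, lowers its count further. In simulated data of the same size the unblocked test found 0% of genes changed 4-fold and 22.4% of those changed 8-fold, and the blocked test 45.1% and 63.6%. Neither found any of those changed 2-fold. The 0 calls therefore leave 2-fold changes unseen in both tests, and 4-fold changes in the unblocked one.

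At least 2-fold apart in the same direction in all 3 lines were 17 genes, 16 higher and 1, MFAP2, lower in CD24+ cells. Among those higher were LOC390705 (1.87 ± 0.51), the zinc finger genes ZNF169 (1.74 ± 0.65) and ZNF493 (1.76 ± 0.54), ZNF433-AS1 (2.26 ± 0.81), the small GTPase RAB4B (2.17 ± 0.94) and the transcriptional regulator IRF2BP1 (1.45 ± 0.32). With the sign of ARP1, OCI-MY5 or OPM2 turned, the same rule gave 9, 15 and 14 genes, so at this limit the 17 exceed the other patterns by little. At 1.5-fold the count was 130 (120 higher, 10 lower) against 90, 74 and 85, an excess beyond the counting spread. Quantile normalization gave 75 (56 higher, 19 lower) against 81, 65 and 77, and centring each array on its median 82 (35 higher, 47 lower) against 73, 81 and 72, so neither the excess nor the direction holds across scalings. All 17 lay in the lowest 25% of tested genes by mean intensity, and 15 in the lowest 10%. The count depended on the treatment of dim signals: it was 32 with a pseudocount of 1, 2 with 64, and 0 with the brightness limit at the 75th percentile. The other genes named by the same ranking were lower in CD24+ cells in each line, by mean differences of −1.49 ± 0.71 for LINC02604 (0.20 without OCI-MY5, and 0.33 without its CD24+ array, where another of its probe sets, higher in the CD24+ cells of OPM2 by 0.96, is the brightest), −1.13 ± 0.86 for ZSWIM5, −0.97 ± 0.44 for GAS7, −0.84 ± 0.36 for GK5 and −0.81 ± 0.12 for CLCA4-AS1.

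**Figure D2:**
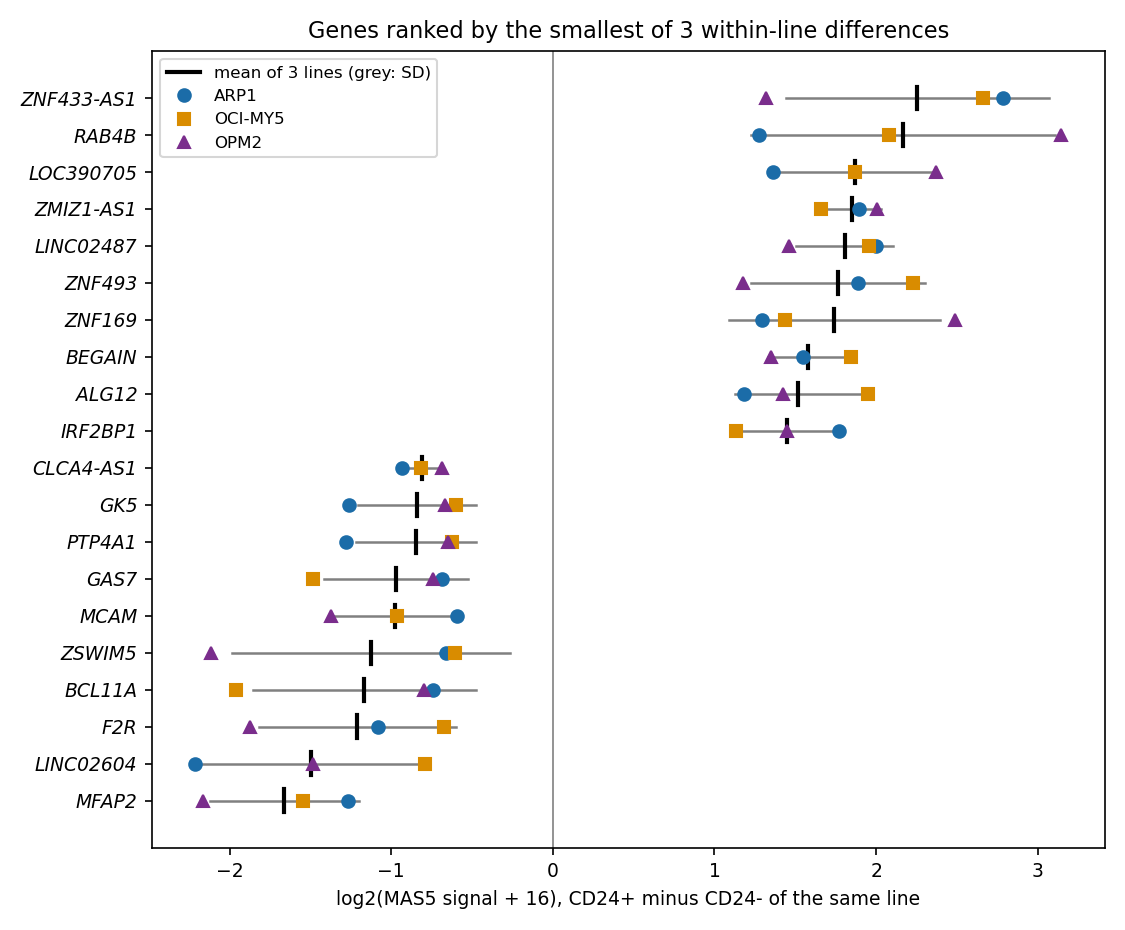
Log2 difference in MAS5 intensity (pseudocount 16) between the CD24+ and CD24− arrays of each line, for the 10 genes higher and the 10 lower in all 3 lines with the largest minimum difference; black bars are means of the 3 lines and grey lines ± 1 SD. The means run from −1.66 for MFAP2 to 2.26 for ZNF433-AS1, and none of these genes passed the adjusted test.

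With a preset correlation between genes 3 lists passed camera's test, and none did with an estimated correlation (adjusted p = 0.949 for each). Relative to all tested genes the median difference was 0.25 for cytosolic ribosomal proteins (0.02 with quantile normalization), 0.21 for genes of G2 and mitosis, which were not higher in OCI-MY5, and −0.18 for genes of DNA replication. These values are alike on the deposited scaling and with each array centred on its median, which moves every gene by the same amount: the median of all tested genes went from 0.03 to −0.30 and the medians of all 30 lists below 0. The 36 ribosomal protein genes tested had a median difference of 0.28 on the deposited scaling (−0.05 after centring) and rose as a list against the other genes (camera, adjusted p = 9.4e-07 with a preset correlation between genes, 0.949 with an estimated one). The call held after centring (adjusted p = 0.0187). On the deposited scaling 24 of them were higher in all 3 lines and 1 was lower in all 3. RPS28 was higher by 0.54 ± 0.54, RPS24 by 0.50 ± 0.59 and RPS18 by 0.48 ± 0.44. The median was 0.65 in OPM2, 0.16 in ARP1 and 0.10 in OCI-MY5, and the OPM2 CD24+ array is the one with the high spike-ins. Its ACTB 3′ over 5′ ratio of 27.1 was the highest, but that of the OCI-MY5 CD24− array was 23.2. The call was lost without OPM2 (median 0.14, adjusted p = 0.0907), and after quantile normalization between arrays the list's median was 0.02 (adjusted p = 0.923), with 16, 23 and 20 of 36 members higher in ARP1, OCI-MY5 and OPM2.

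The 30 G2/M genes had a median difference of 0.24 (−0.09 after centring) and rose as a list against the other genes (camera, adjusted p = 0.00285, or 0.949 with an estimated correlation). The median was 0.39 in ARP1, where 29 of 30 were higher, 0.27 in OPM2, where 24 were, and −0.04 in OCI-MY5, where 13 were. AURKA, a mitotic kinase, was higher by 0.47 ± 0.36, UBE2C, which charges the anaphase-promoting complex with ubiquitin, by 0.45 ± 0.47, NUSAP1, a spindle protein, by 0.39 ± 0.24, and the proliferation marker MKI67 by 0.38 ± 0.28. The call held with quantile normalization (median 0.29, adjusted p = 6.7e-07) and without OPM2 (median 0.21, adjusted p = 0.00072), and was lost without a filter on dim genes (adjusted p = 0.247), without ARP1 (median 0.14, adjusted p = 0.643), without its CD24+ or CD24− array alone (0.291 and 0.415) and after centring (adjusted p = 0.181). Fits without 1 array set unequal lines against each other.

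The 26 genes of G1/S and DNA replication had a median difference of −0.15 and fell as a list (camera, adjusted p = 0.0156; 0.0506 with the cell line as a block and 0.949 with an estimated correlation). The median was −0.04 in ARP1, −0.05 in OCI-MY5 and −0.31 in OPM2, and 9 genes were lower in all 3 lines. Among random lists of equally bright genes, described below, it lay at the 29.3th, 33.5th and 0.11th percentile in the same order. Only in OPM2, whose CD24+ array has the high spike-ins, did it fall below such lists. The call was lost without OPM2 (median −0.07, adjusted p = 0.872), without either OPM2 array (0.145 without CD24+, 0.546 without CD24−), the ARP1 CD24+ array (0.382) or the OCI-MY5 CD24− array (0.267), and with quantile normalization (0.487), and held after centring (0.0325). Here too the fits without 1 array set unequal lines against each other. UNG, a DNA repair glycosylase, differed by −0.52 ± 0.55, the cyclin CCNE2 by −0.40 ± 0.34, and the replication licensing factors CDT1 and CDC6 by −0.37 ± 0.26 and −0.35 ± 0.27. A list of proliferation and drug resistance genes of high-risk myeloma, which shares AURKA with the G2/M list, did not pass (22 genes, median 0.11, adjusted p = 0.751). In it ASPM was higher by 0.39 ± 0.27 and KIF14 by 0.36 ± 0.20. Inhibitors of cyclin-dependent kinases and quiescence genes did not pass either (17 genes, median −0.09, adjusted p = 0.603). CDKN2D differed by 0.49 ± 0.20 and CDKN1C by −0.44 ± 0.38.

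The preset correlation of camera was 0.01. With fry, which asks whether a list differs from no change and not from the other genes, no list passed either (adjusted p = 0.98 for each of the 3). No member of any list passed the gene test, and adjusted over the list alone 0 passed without the block and 1 with it, the Notch ligand DLL4 (1.14 ± 0.25, adjusted p = 0.0429 over its list). Of the list members named here, BCL11A, CIITA, DLL4, FAS, GAS1, OAS3, SFRP1 and SHH had both arrays of 1 line within the range of the TrpnX controls, so their differences there are uncertain.

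No list of genes tied to stem cells or drug efflux, the subject of the study, passed the test. Of the surface markers used for cancer stem cells, 9 were tested, with a median of 0.14. Among them ALCAM was higher by 0.37 ± 0.29, the chemokine receptor CXCR4 by 0.28 ± 0.23 and NCAM1 by 0.28 ± 0.16. The 8 ABC transporters tied to drug efflux had a median of 0.17, with ABCC1 at 0.22 ± 0.13 and ABCC4 at 0.08 ± 0.05. The 13 aldehyde dehydrogenases had a median of −0.04, with ALDH16A1 at 0.39 ± 0.30 and ALDH5A1 at −0.22 ± 0.10. The 7 pluripotency factors bright enough to test had a median of 0.12, which became −0.10 after quantile normalization, and KLF5 was lower in every line, by −0.40 ± 0.02. The Notch list (18 genes) had a median of 0.10. The Wnt list (26 genes) had a median of 0.04, with the Wnt antagonist SFRP1 at 0.89 ± 0.29. The Hedgehog list (12 genes) had a median of −0.11, with the ligand SHH at 0.85 ± 0.27 and GAS1 at −0.73 ± 0.72. Camera's adjusted p for these 7 lists ran from 0.619 to 0.894.

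The lists of plasma cell and B cell identity and of protein quality control did not pass either. The 23 plasma cell genes had a median of −0.05, with XBP1, the transcription factor of secretory cells, at −0.28 ± 0.16, CD38 at −0.20 ± 0.14 and MZB1 at 0.25 ± 0.11. The 18 B cell genes had a median of 0.03, or −0.09 after quantile normalization, and held members on both sides: SPIB was higher by 1.47 ± 1.02 and CIITA by 0.81 ± 0.34, while BCL11A was lower. Of the genes for protein quality control, proteasome subunits had a median of −0.07 (30 genes, adjusted p = 0.207), with PSMC6 at −0.27 ± 0.26. Their median was −0.30 in OPM2, and they passed without ARP1 (median −0.16, adjusted p = 0.0256). The unfolded protein response had a median of −0.10 (31 genes), with DDIT3 at 0.42 ± 0.17, and heat shock proteins of −0.00015 (15 genes), with DNAJB6 at −0.23 ± 0.11.

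None of the inflammatory, survival and metabolic lists passed. NF-κB genes had a median of 0.15 (24 genes, adjusted p = 0.603; 0.14 with the block), with LTB at 0.69 ± 0.04 and RELB at 0.56 ± 0.43. Interferon-stimulated genes had a median of 0.18 (20 genes), with IFIT3 at 0.53 ± 0.33 and OAS3 at −0.81 ± 0.50. Genes of the BCL2 family and caspases had a median of 0.10 (26 genes), with the death receptor FAS at 1.15 ± 0.89, BMF at 0.63 ± 0.23 and BCL2 at 0.43 ± 0.32. Genes of adhesion and mesenchymal transition had a median of 0.13 (22 genes), with fibronectin, FN1, at 0.65 ± 0.31. Immediate early genes had a median of 0.04 (21 genes), with NR4A1 at 1.60 ± 1.98, of which 3.87 came from OPM2. Medians were −0.12 for cholesterol synthesis (17 genes), −0.02 for iron and redox genes (22), 0.02 for the respiratory chain (34) and 0.01 for hypoxia and glycolysis (25), the last −0.02 after quantile normalization. They were 0.06 for DNA repair (31) and 0.02 for Polycomb and DNA methylation (26). WRN, a helicase of DNA repair, was lower by −0.41 ± 0.07, and the Polycomb protein CBX7 was higher by 0.61 ± 0.14.

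Markers of other cell types showed no common direction over the lines. The 6 epithelial markers tested had medians of −0.21, 0.29 and 0.39 in ARP1, OCI-MY5 and OPM2, and the 6 myeloid markers of −0.05, −0.70 and 0.90; the overall medians, 0.11 for both lists, fell below 0 after quantile normalization (−0.09 and −0.05). Lists of T and NK cells, of red cells and platelets, and of stroma and endothelium had 3, 2 and 3 genes above the brightness limit, too few to test. Over the 27 lists that did not pass, medians ran from −0.12 to 0.18 and the lowest adjusted p was 0.207. In 6 of these the median was above 0 while camera, which sets a list against all other genes, pointed down: pluripotency, DNA repair, Polycomb, hypoxia, immediate early genes and the respiratory chain.

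**Figure D3:**
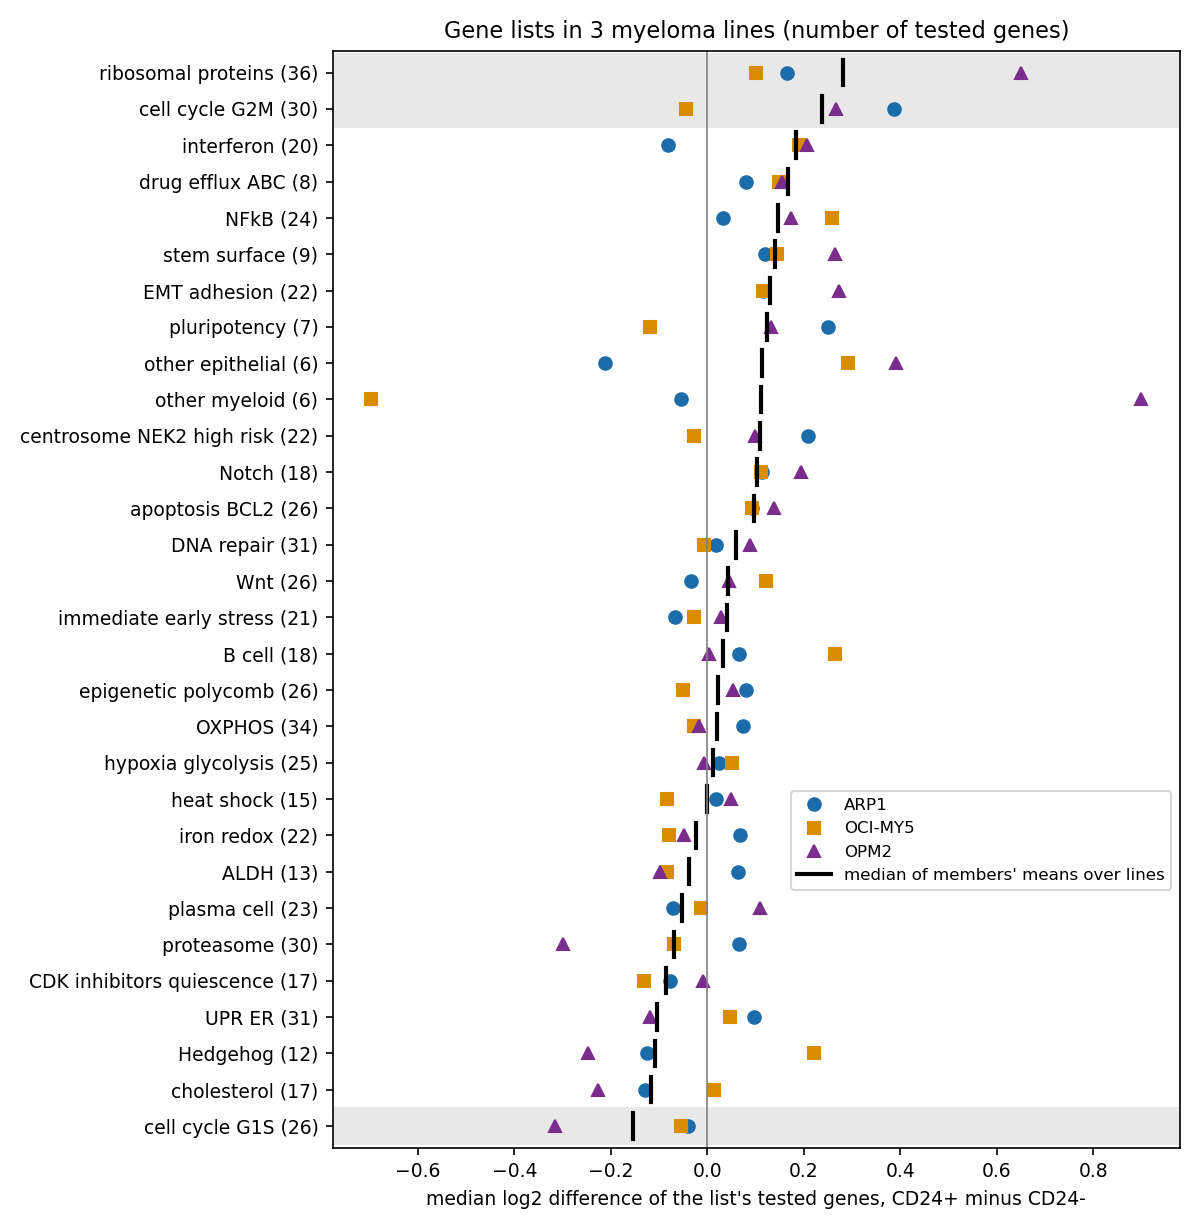
Median log2 difference between CD24+ and CD24− arrays over the tested genes of each of 30 lists, per line (circles ARP1, squares OCI-MY5, triangles OPM2) and as the median of the members' means over the 3 lines (black bars); grey bands mark the 3 lists past camera's adjusted p with the preset correlation. The ribosomal list has medians of 0.16, 0.10 and 0.65 and the G2/M list 0.39, −0.04 and 0.27 on the deposited scaling; centring each array on its median puts all 30 overall medians below 0, and quantile normalization leaves the ribosomal list at 0.02.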

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

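Of the tests below, those of RNA degradation, of the calls without OPM2, of G2/M genes in every line and of the other sign patterns were chosen after the result was seen, as was the matching of lists to the 10 nearest genes by level. The rules for reading 3 of them were also revised after their values were seen: those on the OPM2 CD24+ array and on single probe sets from support for the explanation to an open reading, and that on G2/M genes in every line from exclusion to an open reading.

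The spike-in transcripts, which belong to no comparison between the fractions, had an intensity on the OPM2 CD24+ array 5.36 times the median of the other 5 arrays, and the ribosomal protein genes, the brightest of the lists called, had an OPM2 median of 0.65. A candidate explanation is a difference between arrays that grows with brightness: among 10000 random lists matched gene by gene to the 10 nearest genes in mean level, the ribosomal median in OPM2 lay at the 77.2th percentile (random median 0.61), and quantile normalization left 0.02. A first matching to the 100 nearest genes had put it at the 99.97th percentile, but those genes were dimmer (mean log2 value 15.1, against 15.6 for the ribosomal genes), so that bound was not a fair one. RNA degradation as the source in all lines would put the list lower in the CD24+ cells of OCI-MY5, where the CD24− array has the higher 3′ over 5′ ratio. The list was higher there, at the 99.97th percentile of matched lists (0.10 against 0.06), or the 98.5th with quantile normalization (0.025). This goes against degradation but cannot exclude it. The margin is small, it comes from 1 pair of arrays, and random lists redraw genes and hold no noise between arrays. In ARP1 the list rose no more than equally bright genes (0.16 against 0.18, the 17.2th percentile). With the 100 nearest genes, which were dimmer, it lay at the 87.8th. The random lists left out only the list's own members, so ribosomal protein genes outside the list could be drawn. Such draws were not counted and would hide part of an excess of the list. Whether the call rests on the OPM2 CD24+ array stays open. With the block and without OPM2 the list missed the threshold, as this explanation predicts, but narrowly and on fewer arrays (camera, adjusted p = 0.0575). Without that array alone the adjusted p was 0.0134. That fit had no block and left the other OPM2 array unpaired, which adds a difference between lines, so it does not argue against the explanation.

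G2/M genes had a median of −0.044 in OCI-MY5 and of 0.39 and 0.27 in ARP1 and OPM2, a difference between lines that was not tested. The OPM2 CD24+ array is argued against as the only source of the call, since with the block and without OPM2 camera's adjusted p was 0.00317 (preset correlation). That fit rests on the ARP1 pair, as OCI-MY5 did not rise. It cannot tell whether the rise in OPM2 comes from its CD24+ array. A brightness-dependent difference between the ARP1 arrays is argued against too, since the ARP1 median lay at the 100th percentile of matched lists (random median 0.05). Whether more cells in G2 or mitosis in the CD24+ fraction of every line are the source stays open: OCI-MY5 lay at the 33.2th percentile, inside the range of matched lists (−0.10 to 0.05), with 13 of 30 members higher, on 1 pair of arrays. A higher share of such cells in the CD24+ fractions of ARP1 and OPM2 may be the source, a hypothesis; no biological explanation, culture density or sort gate was tested, and the call is lost with an estimated correlation.

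The 17 genes at least 2-fold apart in all 3 lines could be chance alignments of dim signals, since turning the sign of OCI-MY5 gave 15, within the counting spread of 17. At 1.5-fold, on the deposited scaling alone, the 130 genes exceed the 74 to 90 of the other patterns by more than that spread; with quantile normalization they were 75 against 65 to 81. Of 17 other probe sets for 8 of these genes, 11 had the gene's direction and 4 had it in all 3 lines. Their median was 0.41 in the gene's direction. Even signs would give 12.5% in all 3 lines, but signs were not even on the deposited scaling. Each CD24+ array had the higher median intensity, by 0.14 in ARP1, 0.12 in OCI-MY5 and 0.90 in OPM2. These 8 genes were all higher in CD24+ cells, so neither value speaks for the genes. Only 3 of the 17 reached the brightness limit, of which 1 had the gene's direction and 2, both of HELB (named after its values were seen), the opposite one. With so few, whether the differences belong to the genes or to single probe sets cannot be told apart.

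On its brightest probe set, itself below the brightness limit, CD24 differed by −0.49 in ARP1 and by 2.16 and 0.63 in OCI-MY5 and OPM2, a difference between lines that was not tested. The means over its 6 probe sets were −0.95, −0.12 and 0.61, with 3 of 6 higher in OCI-MY5, so no direction is read from it.

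The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. A real count of 0 genes past adjusted p is reached by all 10 splits whatever their values (highest of the others 0), so that count says nothing. For genes at unadjusted p below 0.05, 7 of the 10 splits reached the real count of 149, and the highest other count was 1447, in the split of the OPM2 pair with 1 ARP1 array against the rest; such splits follow the lines. For gene lists 7 splits reached the real 3 calls, and the highest other count was 5. Among the 4 splits that part every pair, the real one gave 149 genes and the others 91 to 100 without the block. Fitted with it, the real one gave 560 genes at unadjusted p below 0.05 and 2 lists. The others then gave 389 to 434 genes and 1 to 2 lists. All splits used the deposited scaling, on which each CD24+ array had the higher median intensity. With quantile normalization the real split gave 102 genes without the block and 490 with it, and with centring 84 and 631. The other splits were not run on those scalings.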

How the results depend on the processing

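Fits that leave out a line together with the block, the estimated correlation without OPM2, and sign patterns and directions of unadjusted counts under other scalings were chosen after seeing the data. The count of genes past adjusted p stayed at 0 under every alternative run, the block included, with 17 to 633 genes at unadjusted p below 0.05. With the cell line as a replicate block, lists past adjusted p went from 3 to 2 (G1/S lost), DLL4 passed when adjusted over its list alone, and no other call changed. Lists numbered 1 without a filter on dim genes (ribosomal) and 1 with quantile normalization (G2/M), 1 with the block and without OPM2 (G2/M), 1 to 4 when a line or an array was left out, and 0 with an estimated correlation, with fry, with the block and either of these, and with an estimated correlation without OPM2. The G1/S call was also lost with the mean of all probe sets of a gene (adjusted p = 0.0933). Proteasome genes joined the calls without ARP1 (adjusted p = 0.0256), its CD24− array (0.00547) or the OCI-MY5 CD24+ array (0.00095). So did unfolded protein response genes without the ARP1 CD24+ (0.019) or OCI-MY5 CD24− array (0.0217), immediate early genes without the former (0.0358), and interferon genes without the OPM2 CD24+ array (0.0272). The fits without 1 array had no block and set unequal lines against each other. Lists that joined there are not read as differences between the fractions.

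Genes at least 2-fold apart the same way in every line numbered 32 and 2 with pseudocounts of 1 and 64, 166 without a filter, 0 with the filter at the 75th percentile, 10 with quantile normalization, 5 with median centring and 10 with the mean of probe sets. They numbered 130 at 1.5-fold, 1 at 3-fold (ZMIZ1-AS1), and 33 to 155 without a line, when only 2 lines had to match. The mean correlation between lines, 0.034, became 0.044 with a pseudocount of 64, 0.012 without a filter, 0.076 at the 75th percentile, 0.022 with quantile normalization, and 0.036 to 0.044 without a line.

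The share of variance by line, 77.5%, became 76.7% and 78.5% with pseudocounts of 1 and 64, 61.7% without a filter, 84.4% at the 75th percentile, 78.8% with quantile normalization, 63.2% with median centring and 73.5% with the mean of probe sets. The share by fraction, 4.76%, became 6.88% without a filter, 3.66% at the 75th percentile, 11.3% with median centring and 5.46% with the mean of probe sets. Without a line, which leaves fewer arrays per gene, the shares were 66.1% to 66.7% and 10.2% to 11.3%. The CD24 transcript missed the threshold throughout, at 0.07 to 1.39 when a line or array was left out.

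Of 363 values of the 20 genes named by rule under alternatives, 357 kept their sign. Much of this was fixed in advance: the block, the intensity trend and the filters leave a gene's difference as it is. The rule picks genes with the same direction in every line. Leaving out a line can therefore turn a sign only where another probe set becomes the brightest. With the mean of all probe sets the 5 genes with several that were still tested all shrank, PTP4A1 from −0.85 to −0.01. LINC02604 ran from −1.74 to 0.33 when a line or array was left out, and stood at 0.20 with the block and without OCI-MY5, because another of its probe sets was then the brightest. BCL11A ran from −2.54 to 0.13 and F2R from −2.85 to 0.76 in unblocked fits without 1 array, which set unequal lines against each other. The cause of the other changes was not tested. Signal over background limits CD24 and the genes at least 2-fold apart in all lines, which are dim.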

Other observations

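The comparisons between lines and the genes named for them were chosen after the files were opened; the list of translocation and marker genes was written before its values were seen, and CXCL10, FOS, FOSB, JUN, DUSP1, IGFBP7, S100A4, TSC22D3, XYLT1 and GNLY were picked after theirs were.

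OPM2 carried the transcripts known from myeloma with the t(4;14) translocation, which activates FGFR3 and NSD2. FGFR3, a receptor tyrosine kinase, had intensities of 55028 and 44707 in the CD24+ and CD24− cells of OPM2, against 58.7 to 383 in the other lines (log2 difference 6.997 from OCI-MY5, limma adjusted p = 0.00361, 2 arrays per line). NSD2, a histone methyltransferase, had 8911 and 7508, against 2303 to 4454 (log2 difference 1.06 from ARP1, limma adjusted p = 0.0403, or 0.0905 without the OPM2 CD24+ array; 1.77 from OCI-MY5, adjusted p = 0.014, or 0.0352). MAF, a transcription factor activated by another translocation of myeloma, was lower in OPM2, with 2295 and 2665 against 7032 to 9833 elsewhere (log2 difference −1.68 from ARP1, limma adjusted p = 0.0134). Yet ITGB7, a known target of MAF, was higher in OPM2, at 14170 and 18116 against 4757 to 7048, by a log2 difference of 1.75 from ARP1 (adjusted p = 0.0244). Of the other MAF targets on the list, CCR1 was higher by 1.18 (adjusted p = 0.0342, or 0.0785 without the OPM2 CD24+ array) and NUAK1 differed by 0.33 (adjusted p = 0.278). NCAM1 was higher in OPM2 than in ARP1 by 2.66 (adjusted p = 0.00641).

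ARP1 and OCI-MY5 were closer to each other than either was to OPM2. The identity of the lines was not checked here, so how far these 2 count as separate lines is not known. Levels of the tested genes correlated at 0.93 to 0.94 between arrays of ARP1 and OCI-MY5 and at 0.79 to 0.84 between either and OPM2. With line and fraction in 1 limma model, 6 genes differed between OCI-MY5 and ARP1 at adjusted p below 0.05, 2396 between OPM2 and ARP1 and 2611 between OPM2 and OCI-MY5 (2008 and 2075 without the OPM2 CD24+ array, 6 again for the first). The replicates of a line here are its CD24+ and CD24− arrays, so these p-values rest on no repeated culture. Both arrays of a line lay at least 2-fold beyond both of the other for 698 genes between ARP1 and OCI-MY5, 1807 between ARP1 and OPM2 and 1891 between OCI-MY5 and OPM2. The 6 genes were CXCL10, an interferon-induced chemokine with intensities of 7960 and 4757 in OCI-MY5 against 10.2 and 2.49, near background, in ARP1, and FOSB, IGFBP7, S100A4 (log2 difference −4.16), TSC22D3 and XYLT1, lower in OCI-MY5. No size is given for the others, which were dim in 1 of the lines. Other immediate early genes were bright in ARP1 as well: FOS had intensities of 8407 and 9394 there, against 11.9 to 202 elsewhere, and DUSP1 23170 and 24889, against 502 to 1181. GNLY, a protein of cytotoxic lymphocyte granules, had 5215 and 6859 in ARP1, against 5.51 to 119 in the other lines.

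Different probe sets of a gene agreed little on the difference between the fractions. Across 5887 genes with at least 2 probe sets above the brightness limit, the differences of the brightest pair correlated at r = 0.076 in ARP1, 0.166 in OCI-MY5 and 0.148 in OPM2, across genes, which are not independent replicates.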
